A study of Mus musculus with 3 samples.

How the data were processed

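Single cells of 3 MMTV-PyMT mammary tumours, 1 per mouse, had been sorted as CD45+ Ly6G- CD11b+ F4/80+ and sequenced with a 10x 3' v3 kit. Per the file headers and the labels, the authors made the deposited matrices with Cell Ranger 3.0.2 on build mm10, and their values are raw UMI counts per gene and barcode of barcodes already called as cells. The version of the gene annotation was not given in the sources used here. Each matrix had 31053 features, and 35 symbols were shared by more than 1 gene ID, whose counts were kept apart. Gene positions came from the GENCODE mouse annotation of the same build by gene ID.

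Cells were kept with at least 500 genes and at most 15% mitochondrial UMIs, which removed 411, 362 and 451 barcodes of mice 1, 2 and 3. Scrublet in scanpy 1.11.5 (Python 3.11.15) then called 11 doublets (0.113% of cells), too few for a working caller, so removal at 0.8% per 1000 cells was added as an alternative. The 2000 most variable genes were chosen within mice, each gene was scaled within its mouse, and Leiden clustering at resolution 1.0 used 15 neighbours in 30 principal components. Genes of 14 function lists (377 genes, 371 in the files), ribosomal protein genes and mitochondrial genes were left out of clustering. Clusters were named from 24 marker lists (191 genes, 190 in the files) when at least 5 markers of a list were detected in 10% of the cluster's cells or more and lay 0.5 or more above the other clusters on the log2 scale, and no other list had as many markers, and at least 1, among the 10 leading genes. Cluster 12, whose 293 cells joined the cycling-like class, was named on 5 markers with 0 of them among its leading genes. A cluster with few UMIs also needed a marker of the list among those genes. Marker genes define clusters and are not results. The macrophage lineage list was used neither to name clusters nor to choose the classes of the fits. Classes named for another lineage stayed out. All others, 14 of 16, were taken as macrophage classes, numbered clusters included, without a test of macrophage markers.

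UMI counts were summed per mouse and class. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, robust quasi-likelihood F test, 2-sided), with class and mouse as terms, the contrast being the class minus the unweighted mean of the other classes. The SE of a log2 fold change was its size divided by the square root of F. Adjustment followed Benjamini and Hochberg over the 8379 genes that had not been used to cluster (8632 in the 3-cell fit), with a threshold of 0.05 in each class. CPM of a class is given as mean and SD over the mice. Function lists were tested with camera in limma 3.58.1 on the edgeR fit, with a correlation of 0.01, adjusted over the 140 pairs of list and class of the 20-cell fit and over all pairs in the 3-cell fit. The fit required 20 cells of a class in each mouse, and the 3-cell minimum was added after seeing the data.

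The genes named in the text follow a rule fixed before the data were examined. Within the lists they passed the threshold with the same sign in 3 of 3 mice, and were among the 16 largest higher and 8 largest lower for the LYVE-1 resident-like class and 8 and 4 for other classes. Outside the lists they were among the 3 largest in each direction at 50 CPM or more, predicted genes excluded. Genes of the gate, and Mrc1, Stab1, Hmox1, Pdgfc, Vegfa, Ccl8, Pf4 and Igf1 in the LYVE-1 resident-like class, were given whatever their result. Genes of that rule with fewer than 5 UMIs in the class are not named, and some others are left out.

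Alternatives covered the cell filters, doublets, clustering, normalization (DESeq2 1.42.0 size factors), the DESeq2 Wald test, the filter on low counts, the mouse block, equal cell numbers, the reference of the contrast, clusters and tests on separate UMIs, each mouse left out, an estimated correlation and fry. The fit was tested on simulated data with known changes: log2 changes of 0.5, 1 and 2 were called for 59.02, 92.2 and 100% of changed genes in the inflammatory-like class and for 10.4, 36.4 and 74.6% in the LYVE-1 resident-like class. False calls made up 4.73% of calls in the inflammatory-like class, 3.70% in the LYVE-1 resident-like class, 6.18% in cluster 2 and 8.70% in cluster 14, against a nominal 5%. In each simulation, drawn once, the classes of a mouse had the same mean profile apart from changed genes in a single class. The real classes differ in many more genes, so these rates need not hold for the real comparisons. Intervals for shares of cells are exact (Clopper-Pearson, 95%), and limits for a count of 0 take 3 counts. Cells of other lineages were left out of the fits. Data other than the count matrices were not analysed here.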

Results

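Tumour-associated macrophages of 3 MMTV-PyMT mice were profiled by droplet single-cell RNA sequencing, which counts unique molecular identifiers (UMIs) at the 3' ends of transcripts. In this strain the polyoma middle T oncogene drives tumours of the mammary epithelium. One tumour of 750 mm3 was taken from each mouse, and its cells were sorted for CD45, CD11b and F4/80 and against Ly6G. The 3 libraries formed 1 group with the mouse as replicate, so no contrast between samples existed. The comparisons were made between classes of cells within the mice. The libraries of mice 1, 2 and 3 held 1074, 2470 and 7429 barcodes with 12454677, 41097369 and 86178419 UMIs. Filters on detected genes, mitochondrial UMIs and doublets left 661, 2099 and 6978 cells with medians of 14996, 13579 and 9318.5 UMIs. More than 15% mitochondrial UMIs were found in 36.03% of the barcodes of mouse 1, 12.1% of mouse 2 and 4.13% of mouse 3.

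The genes behind the sort were detected in most cells. Ptprc, which encodes CD45, had a UMI in 91.8% ± 2.13 of the cells (mean ± SD, n = 3 mice). Adgre1, which encodes F4/80, had one in 86.5% ± 1.62, and Itgam, which encodes CD11b, in 67.1% ± 2.95. No UMI of the neutrophil gene Ly6g was found in the 661, 2099 and 6978 cells, which allows shares of cells with a UMI of up to 0.454, 0.143 and 0.0430%. In build mm10, Ptprc lies on chromosome 1, 138062861 to 138175708, minus strand, Itgam on chromosome 7, 128062640 to 128118491, plus strand, Adgre1 on chromosome 17, 57358691 to 57483527, plus strand and Ly6g on chromosome 15, 75155240 to 75159126, plus strand. With each cell thinned to 2000 UMIs, the shares were 55.2% ± 10.1 for Ptprc, 44.1% ± 4.24 for Adgre1 and 24.4% ± 1.09 for Itgam. For comparison, the same genes were read in 54 tumour epithelium-like cells, with up to 14 Ptprc, 6 Adgre1 and 5 Itgam UMIs in a cell. Whether these UMIs came from free RNA or from attached macrophages was not tested. The median of these cells was 3353.5 UMIs. Their shares were 20.4% for Ptprc, 16.7% for Adgre1 and 7.41% for Itgam as sequenced. After thinning, 36 of these cells remained, with shares of 11.1% for Ptprc and 2.78% for Adgre1, and with 0 cells for Itgam, which allows up to 8.33%.

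Genes of other cell types were detected in few cells, apart from a milk protein gene. Shares of cells with a UMI were 0.0890% ± 0.130 for the T cell gene Cd3e, 0.0254% ± 0.0240 for the B cell gene Cd79a and 0.00478% ± 0.00827 for the natural killer cell gene Ncr1. They were 0.483% ± 0.271 for the dendritic cell gene Flt3, 1.52% ± 0.797 for the neutrophil gene S100a8, 2.36% ± 0.733 for the fibroblast gene Col1a1 and 1.06% ± 0.460 for the endothelial gene Cdh5. The haemoglobin gene Hbb-bs had a UMI in 2.51% ± 0.843 of cells and the epithelial gene Epcam in 4.65% ± 1.15. Csn3, which encodes kappa casein, had a UMI in 16.5% ± 2.51 of cells. Its level was 10.2 to 30.6 CPM in the macrophage classes and 16512 CPM in the tumour epithelium-like cells.

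Clustering gave 17 clusters, of which 9 took a name from marker genes, a pair of them the same name, and 8 kept a number. The inflammatory-like class, named by Il1b, Il1a, Tnf and Nlrp3 among others, held 14.9% ± 0.682 of the cells (mean ± SD, n = 3 mice). The lipid-associated-like class (Trem2, Spp1, Fabp5) held 8.30% ± 3.68, the cycling-like class (Mki67, Top2a) 9.68% ± 2.21 and the hypoxia-like class (Bnip3, Hilpda, Arg1) 5.998% ± 1.58. The interferon-like class (Ifit1, Isg15, Rsad2) held 2.91% ± 0.892. The LYVE-1 resident-like class, in which all 12 markers of its list were higher, held 0.840% ± 0.358, or 3, 19 and 81 cells of mice 1, 2 and 3. Exact binomial 95% intervals for these shares were 0.0937 to 1.32%, 0.546 to 1.41% and 0.923 to 1.44%, covering counting error only. The extent of this class followed the clustering: its share was 23.99% at Leiden resolution 0.5 and 27.5% with 4000 variable genes.

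Of the numbered clusters, cluster 2 held 13.6% ± 3.90, cluster 3 10.7% ± 1.92, cluster 7 9.12% ± 2.99, cluster 5 8.20% ± 0.634, cluster 9 5.79% ± 5.32, cluster 10 4.65% ± 1.56, cluster 14 2.83% ± 2.09 and cluster 13 1.77% ± 0.812. Cluster 2 had 7 of the 12 LYVE-1 resident markers higher, Lyve1 and Cd163 included, but kept its number because of a tie among its leading genes. These held 1 LYVE-1 resident marker, Cbr2, and 1 monocyte marker, Ccr2. Tumour epithelium-like cells made up 0.629% ± 0.170 and T cell-like cells 0.165% ± 0.115. No cluster was named by the marker lists for monocytes, MHC-II high macrophages, dendritic cells, neutrophils, natural killer cells, B cells, mast cells, eosinophils, fibroblasts, endothelium, pericytes or erythroid cells. Cluster 9 differed most between mice, at 1.97% of mouse 1, 11.9% of mouse 2 and 3.54% of mouse 3. Without mouse 2 its mean was 2.75%. Cluster 14 had a mean of 1.74% without mouse 1, and T cell-like cells 0.104% without mouse 2. These shares describe cells after dissociation, sorting, capture in droplets and filtering.

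**Figure D1:**
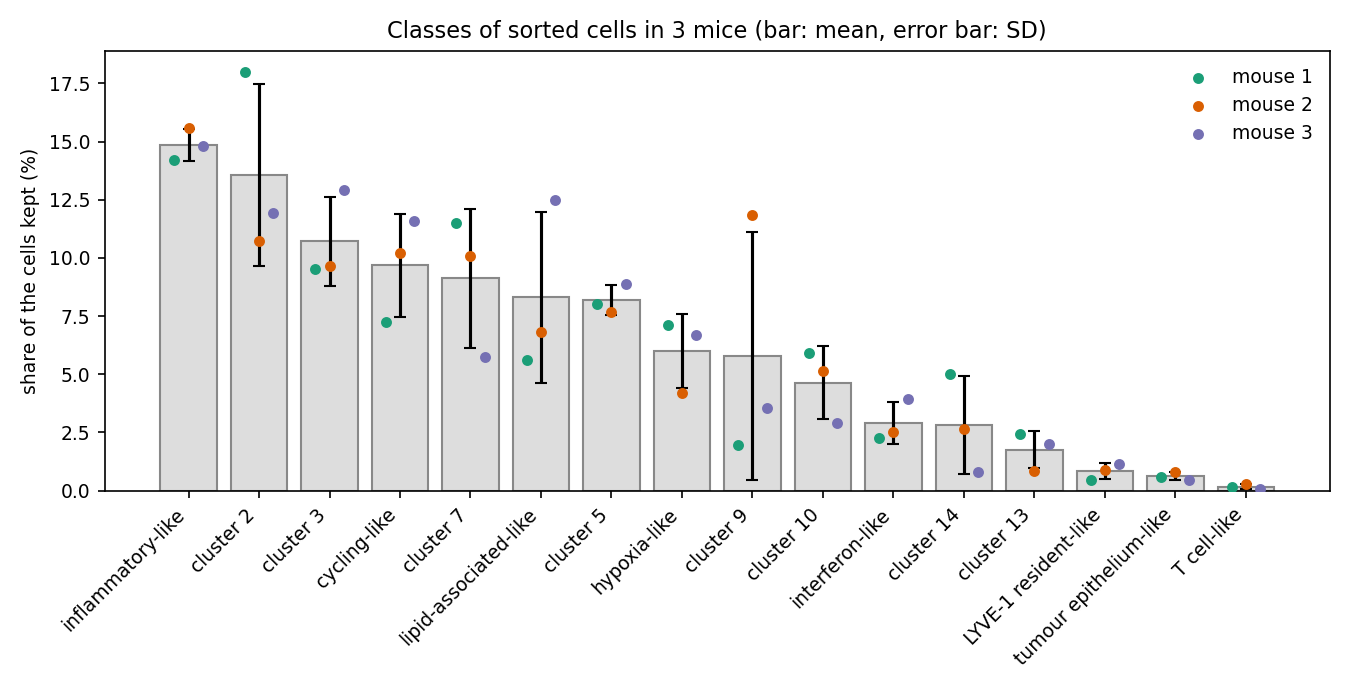
Share of the cells kept, in percent, for each class, with a bar for the mean over 3 mice, an error bar for the SD and a point per mouse. The inflammatory-like class stood at 14.9% ± 0.682 and the LYVE-1 resident-like class at 0.840% ± 0.358, and the widest spread was that of cluster 9.

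Gene comparisons asked how each macrophage class differed from the others. Fold changes are log2 values of a class against the mean log level of the other classes, fitted with the mouse as a block, and are given ± SE. Levels in CPM are means over the mice ± SD. Fold changes differ from the ratio of mean CPM where a few classes hold most of a gene's counts. Genes used to cluster were left out, and 14 function lists had been held out of clustering for these tests. The classes were still formed from the same cells, and genes left out can vary together with genes used to cluster. The p-values therefore do not measure a difference that is independent of how the classes were formed. The genes named below lay on the stated side in 3 of 3 mice and passed edgeR's quasi-likelihood test at 5% after Benjamini-Hochberg adjustment, unless a value says otherwise. Of 14 macrophage classes, 10 had at least 20 cells in each mouse and were fitted together. The LYVE-1 resident-like and interferon-like classes and clusters 9 and 13 had fewer in some mouse, and come from a fit with a 3-cell minimum that was added after seeing the data.

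Macrophages that express LYVE-1, a hyaluronan receptor, are the cells with which the study is concerned, and the comparison asked which genes differed in the class named from markers of such cells. A Lyve1 UMI was found in 83 of its 103 cells, but also in 253 cells of cluster 3, 187 of cluster 2 and 88 of cluster 9, at 21.7, 15.9 and 17.3% of their cells, against 1.85% of the tumour epithelium-like cells. Median UMI counts per cell were 8365 in the class, 20699.5, 7886.5 and 29350 in clusters 3, 2 and 9, and 3353.5 in the tumour epithelium-like cells. With cells thinned to 2000 UMIs the shares were 51.5% in the class, 4.89, 8.48 and 1.78% in clusters 3, 2 and 9, and 2.78% of 36 tumour epithelium-like cells. The LYVE-1 resident-like cells had higher levels of the chemokine genes Ccl8 (4.68 ± 0.33; 7466 ± 3339.9 CPM, SD, n = 3) and Ccl24 (5.87 ± 0.42). Ccl7 (3.18 ± 0.29) and Ccl2 (2.95 ± 0.25), whose products attract monocytes, were higher too, as were Ccl6 (3.33 ± 0.23) and Pf4 (2.77 ± 0.27). Growth factor genes were higher for Igf1 (3.89 ± 0.21), the epidermal growth factor receptor ligand Hbegf (3.51 ± 0.29) and Pdgfc (2.82 ± 0.22; 113 ± 43.3 CPM), which encodes a ligand of the platelet-derived growth factor receptors. Vegfa, which encodes an angiogenic factor, was lower (-1.41 ± 0.36; 28.8 ± 12.3 CPM against 128 ± 10.2 in the other classes), but was called higher in 5 alternative settings: at Leiden resolution 0.5 (0.57, edgeR adjusted p = 1.74e-04), with 4000 variable genes (0.42, adjusted p = 0.0205), at 1000 detected genes (0.73, adjusted p = 0.00207), at 8% mitochondrial UMIs (0.70, adjusted p = 0.00337) and with doublets kept (0.51, adjusted p = 0.0142). At 25% mitochondrial UMIs it was at 0.43 (edgeR adjusted p = 0.0551). The class of that name held mostly other cells in these settings. Cells of the class reported here made up 4.22, 3.70, 5.97, 10.9 and 6.08% of it in the 5 settings, in the order given. At 25% mitochondrial UMIs they made up 5.44%. The values on the higher side therefore describe mainly other cells.

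The scavenger receptor genes Mrc1 (2.64 ± 0.25), which encodes the mannose receptor, and Stab1 (1.12 ± 0.14) were higher in the class. So were the transferrin receptor gene Tfrc (4.69 ± 0.33) and Hmox1 (2.51 ± 0.31; 1498 ± 363 CPM), which encodes the haem-degrading enzyme haem oxygenase 1. F13a1, the gene of a fibrin cross-linking enzyme (4.38 ± 0.27), the complement gene C4b (3.86 ± 0.24), and the transcription factor genes Klf4 (2.89 ± 0.26) and Irf4 (2.66 ± 0.42) were also higher. Lower genes included Itgax, which encodes CD11c (-2.49 ± 0.34), Cd52 (-2.26 ± 0.19), the membrane metalloproteinase gene Mmp14 (-2.23 ± 0.23) and Havcr2, which encodes TIM-3 (-2.21 ± 0.23). Outside the lists, the nucleoside transporter gene Slc28a2 (4.39 ± 0.36), Iqgap2 (3.43 ± 0.33) and Zfyve21 (3.27 ± 0.27) were higher, and Ramp1 (-2.76 ± 0.33), Abi3 (-2.46 ± 0.37) and Parvg (-2.45 ± 0.34) lower, the last 3 on 12 to 13 UMIs in the class. Adjusted p-values from edgeR ran from 3.58e-22 for Igf1 to 0.00437 for Vegfa among the genes named here.

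By function list, 9 of 21 chemokine genes were higher and 2 lower in the LYVE-1 resident-like class, and the same counts held adjusted over the list alone (camera adjusted p = 4.31e-08). Complement genes were 5 higher and 1 lower of 15, with 5 and 1 adjusted over the list alone (camera adjusted p = 5.25e-06). Haem and iron genes were 8 higher and 1 lower of 25, 8 and 1 adjusted over the list alone (camera adjusted p = 1.07e-04, and adjusted p = 0.114 with an estimated correlation). Of 22 growth and angiogenic factor genes 8 were higher and 2 lower, 8 and 3 adjusted over the list alone (camera adjusted p = 0.00131, and adjusted p = 0.114 with an estimated correlation). Camera put this list higher and its mean log2 fold change was 0.45, while its median was -0.08. Dissociation and heat stress genes were higher for 19 of 26, 20 adjusted over the list alone (camera adjusted p = 2.19e-14, and adjusted p = 0.0592 with an estimated correlation). Scavenger and endocytic receptor genes were 13 higher and 5 lower of 31, 15 and 8 adjusted over the list alone (camera adjusted p = 2.88e-05, and adjusted p = 0.165 with an estimated correlation), and transcription factor genes 15 higher and 4 lower of 37, 16 and 4 adjusted over the list alone (camera adjusted p = 8.21e-05, and adjusted p = 0.223 with an estimated correlation). Genes of oxidative phosphorylation were lower for 8 of 30 and higher for 0, 11 lower adjusted over the list alone (camera adjusted p = 1.95e-05, and adjusted p = 0.308 with an estimated correlation), and 20 lower without clusters 10 and 14. Glycolysis genes were lower for 7 of 16 and higher for 2, 10 and 2 adjusted over the list alone (camera adjusted p = 0.00909, and adjusted p = 0.438 with an estimated correlation), and MHC class I and peptide loading genes lower for 4 of 22 and higher for 0, 5 lower adjusted over the list alone (camera adjusted p = 0.0223, and adjusted p = 0.438 with an estimated correlation). The MHC class I call was lost without mouse 1 (camera adjusted p = 0.0766).

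In all, edgeR called 1596 of 8632 genes in this class, 875 higher and 721 lower (833 and 974 without clusters 10 and 14). The count was 954 without mouse 2 and 565 without mouse 3, and mouse 1 gave 3 cells. With 4000 variable genes the class took in 2678 cells, 39.4% of them from cluster 3 and 38.01% from cluster 2, and at 1000 detected genes Mmp14 lay on the higher side (0.14). In mm10, Ccl8 (ENSMUSG00000009185) lies on chromosome 11, 82115185 to 82116799, plus strand, Pdgfc (ENSMUSG00000028019) on chromosome 3, 81036416 to 81214040, plus strand and Vegfa (ENSMUSG00000023951) on chromosome 17, 46016993 to 46032369, minus strand. Mrc1 lies on chromosome 2, 14229392 to 14332057, plus strand, Stab1 on chromosome 14, 31139013 to 31168641, minus strand, Hmox1 on chromosome 8, 75093621 to 75100589, plus strand, Igf1 on chromosome 10, 87858265 to 87937042, plus strand and Pf4 on chromosome 5, 90772435 to 90773383, plus strand.

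**Figure D2:**
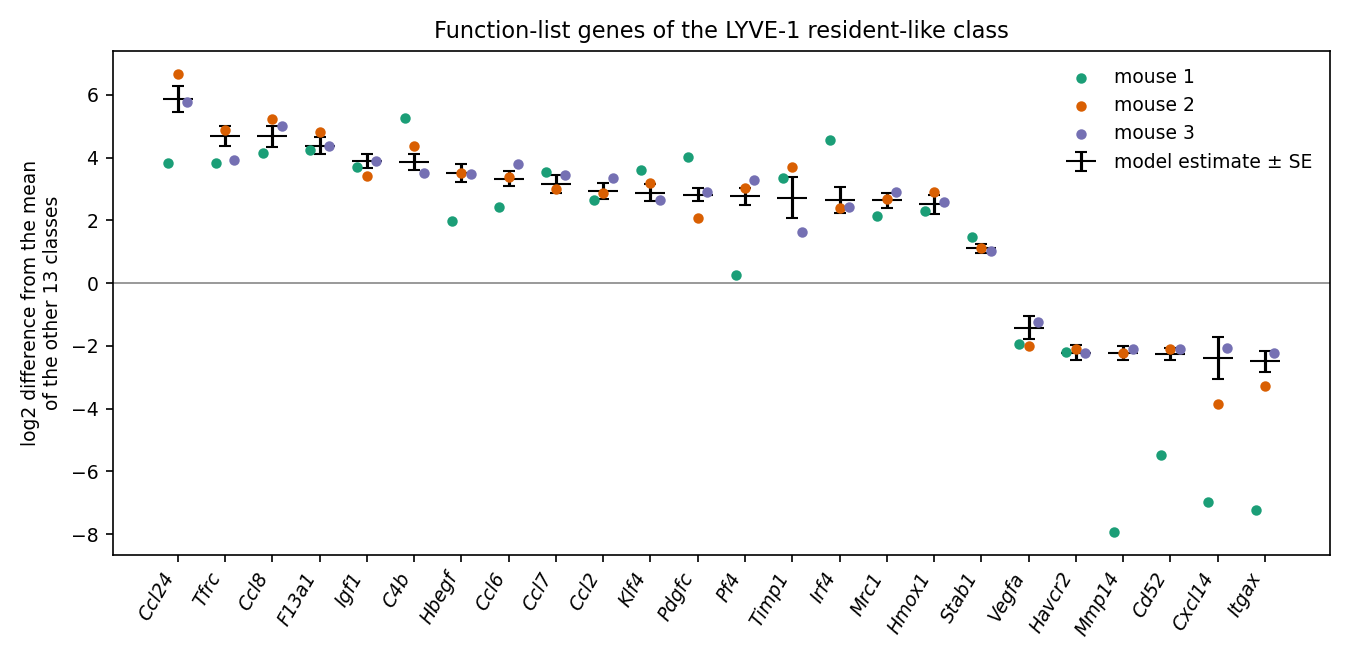
Genes of the function lists in the LYVE-1 resident-like class, with the log2 difference from the mean of the other 13 classes on the vertical axis, a point per mouse, and the model estimate with its SE. All 3 mice lie above 0 for 18 genes and below 0 for 6, and the points of mouse 1 rest on 3 cells.

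In the inflammatory-like cells the chemokine genes with higher levels included Cxcl2 (1.77 ± 0.23; 5848 ± 2738 CPM, SD, n = 3), Cxcl1 (2.06 ± 0.24), Ccl5 (1.82 ± 0.26) and Ccl22 (3.28 ± 0.27; 39.2 ± 11.5 CPM). Ccl8 was lower (-2.81 ± 0.57), lost its call without mouse 2 (-3.09, edgeR adjusted p = 0.0607), and was at 0.05 at Leiden resolution 1.5 and 0.20 with doublets kept. The chemokine list as a whole was not called, with 8 higher and 4 lower of 21, 9 and 4 adjusted over the list alone (camera adjusted p = 0.0520, and adjusted p = 0.392 with an estimated correlation). The epidermal growth factor receptor ligand gene Areg (2.93 ± 0.34) and the antioxidant enzyme gene Srxn1 (2.09 ± 0.14) were higher, and Igf1 (-2.68 ± 0.38) and F13a1 (-3.18 ± 0.53) lower. Beyond the lists Dpys (1.98 ± 0.13) and Osgin2 (1.61 ± 0.11) were higher, as was Bcl2a1d (2.35 ± 0.16), whose counts can mix with those of its near-identical copies. The copies Bcl2a1a and Bcl2a1b were used to cluster, so the test of Bcl2a1d is not independent of how the class was formed. Plxnb2, a semaphorin receptor gene, was lower (-0.91 ± 0.12). Immune checkpoint and regulation genes were 16 higher and 6 lower of 25, 16 and 7 adjusted over the list alone (camera adjusted p = 1.47e-04). MHC class I and peptide loading genes were higher for 12 of 22, 12 adjusted over the list alone (camera adjusted p = 1.12e-04, and adjusted p = 0.177 with an estimated correlation). EdgeR called 1919 of 8379 genes, 77.3% of them higher (57.6% of 2375 with clusters 10 and 14 left out of the reference), against 607 without mouse 2 and 802 without mouse 3. F13a1 was at 0.38 in the class formed when doublets were kept.

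In the lipid-associated-like cells, the lysosomal protease gene Ctsd was higher (1.15 ± 0.12; 5166 ± 783 CPM, SD, n = 3), together with the glycolytic enzyme genes Pgam1 (0.95 ± 0.11), Tpi1 (0.92 ± 0.12) and Gapdh (0.86 ± 0.12). The scavenger receptor gene Colec12 (0.90 ± 0.13), Pld3 (0.86 ± 0.10) and the glycogenin gene Gyg (0.80 ± 0.12) were higher as well. Ciita, the gene of the transactivator of MHC class II transcription, was lower (-1.90 ± 0.21; 7.88 ± 5.14 CPM), as was H2afv (-0.70 ± 0.11). MHC class II accessory genes were lower for 5 of 12 and higher for 0, 6 lower adjusted over the list alone (camera adjusted p = 7.56e-11). Glycolysis genes were higher for 9 of 16, 12 adjusted over the list alone (camera adjusted p = 1.79e-13). Lipid handling genes were 6 higher and 1 lower of 31, 9 and 1 adjusted over the list alone (camera adjusted p = 0.00219, and adjusted p = 0.150 with an estimated correlation), and 10 were higher without clusters 10 and 14. Of 8379 genes edgeR called 666, 81.1% of them higher (53.1% of 772 without clusters 10 and 14), and 57 without mouse 2 and 65 without mouse 3. The ferroportin gene Slc40a1 (1.26 ± 0.36) lost its call without mouse 2 (1.54, edgeR adjusted p = 0.268) and without mouse 3 (1.43, edgeR adjusted p = 0.355).

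The hypoxia-like cells had more transcript of Nt5e, which encodes the ectoenzyme CD73 (2.07 ± 0.19; 44.8 ± 19.2 CPM, SD, n = 3), and of the lactate transporter gene Slc16a3 (1.54 ± 0.18; 217 ± 111 CPM). Trem1, the gene of an activating receptor (2.07 ± 0.21), Plscr1 (2.03 ± 0.21) and Adssl1 (1.31 ± 0.16) were higher and Igf1 lower (-2.67 ± 0.42, on 12 UMIs). Glycolysis genes were higher for 12 of 16 and lower for 1, with the same counts adjusted over the list alone (camera adjusted p = 1.67e-20). Oxidative phosphorylation genes were higher for 22 of 30, 28 adjusted over the list alone (camera adjusted p = 2.30e-18), and for 13 without clusters 10 and 14. Dissociation and heat stress genes were lower for 5 of 26 and higher for 0, 7 and 2 adjusted over the list alone (camera adjusted p = 1.84e-04, and adjusted p = 0.208 with an estimated correlation). The interleukin 1 receptor antagonist gene Il1rn was at 1.38 ± 0.21 and the epidermal growth factor receptor ligand gene Areg at 1.93 ± 0.40. At Leiden resolution 1.5, where the class had 3.11% of cells, these were -0.78 (edgeR adjusted p = 0.00613, a call in the other direction) and -1.54, and Areg lost its call without mouse 2 (2.48, edgeR adjusted p = 0.0543) and without mouse 3 (2.08, edgeR adjusted p = 0.189). EdgeR called 1127 genes, 79.2% of them higher (62.1% of 1008 without clusters 10 and 14), 154 without mouse 2 and 177 without mouse 3.

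Cluster 2 had high levels of chemokine transcripts, with Ccl7 at 4505 ± 881 CPM (3.98 ± 0.25), Ccl2 at 2875 ± 474 CPM (3.49 ± 0.22), Pf4 at 1444 ± 271 CPM (3.17 ± 0.20) and Ccl6 at 1833 ± 539.8 CPM (3.07 ± 0.23; SD, n = 3). Ccl24 (4.62 ± 0.36), F13a1 (3.81 ± 0.27), the cytokine gene Lif (3.62 ± 0.25) and the metalloproteinase inhibitor gene Timp1 (3.64 ± 0.22) were higher, and Itgax (-1.90 ± 0.13) and the chemokine gene Cxcl14 (-1.89 ± 0.35) lower. Outside the lists Igfbp6 (2.72 ± 0.21), Cdc42ep4 (2.53 ± 0.17) and Stx11 (2.14 ± 0.12) were higher, and F11r (-2.08 ± 0.15) and Tnfsf13b (-2.01 ± 0.24) lower. Chemokine genes were 13 higher and 2 lower of 21, the same adjusted over the list alone (camera adjusted p = 2.52e-13). Scavenger and endocytic receptor genes were 21 higher and 3 lower of 31, 22 and 3 adjusted over the list alone (camera adjusted p = 3.66e-13). Growth and angiogenic factor genes were 14 higher and 1 lower of 22, 14 and 2 adjusted over the list alone (camera adjusted p = 8.67e-05). Dissociation and heat stress genes were higher for 13 of 26 and lower for 0, 14 higher adjusted over the list alone (camera adjusted p = 2.16e-05, and adjusted p = 0.150 with an estimated correlation). The edgeR count was 2519 genes, 71.2% of them higher (54.7% of 3235 without clusters 10 and 14), 1469 without mouse 2 and 1426 without mouse 3.

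Cluster 3 had a median of 20699.5 UMIs per cell and the highest median doublet score, 0.113. Its cells were higher for Ccl8 (2.87 ± 0.35; 1628 ± 451 CPM, SD, n = 3), Ccl7 (2.19 ± 0.28), F13a1 (2.47 ± 0.29), Igf1 (2.23 ± 0.13; 43.5 ± 13.8 CPM) and Hbegf (1.76 ± 0.18). Itsn1 (1.07 ± 0.11), a gene of endocytosis, and the adaptor gene Ap1b1 (0.83 ± 0.10) were higher outside the lists. Transcription factor genes were higher for 19 of 36, 24 adjusted over the list alone (camera adjusted p = 1.73e-14). Scavenger and endocytic receptor genes were higher for 15 of 31, 16 adjusted over the list alone (camera adjusted p = 2.79e-10), and dissociation and heat stress genes for 20 of 26, 22 adjusted over the list alone (camera adjusted p = 6.55e-23). None of these lists had a lower member past the threshold. EdgeR called 827 genes, 93.7% of them higher, but 48.5% of 1698 without clusters 10 and 14. The count was 96 without mouse 2, when Ccl8 lost its call (2.59, edgeR adjusted p = 0.0566), and 271 without mouse 3.

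Heat-shock and immediate-early genes led cluster 5. Hspa1a (3.16 ± 0.29; 2046 ± 259 CPM, SD, n = 3) and Hspa1b (3.06 ± 0.35), near-identical copies whose counts can mix, Dnajb1 (2.42 ± 0.15), Jun (2.53 ± 0.16), Fos (2.07 ± 0.14; 2155 ± 142 CPM) and Atf3 (2.23 ± 0.10) were higher. The chemokine gene Ccl3 was higher (2.28 ± 0.35), and the lectin gene Clec4d lower (-2.07 ± 0.30). Abi3 (1.19 ± 0.11) and Tifab (1.15 ± 0.12) were higher outside the lists, and Tnip1 (-1.57 ± 0.17) and Sept11 (-1.13 ± 0.15) lower. Dissociation and heat stress genes were higher for 23 of 26, the same adjusted over the list alone (camera adjusted p = 4.89e-86). The labels give a digestion at 37°C in collagenase I and DNase I before the sort. MHC class II accessory genes were higher for 7 of 12, 9 adjusted over the list alone (camera adjusted p = 4.25e-06), and glycolysis genes lower for 11 of 16 and higher for 1, the same adjusted over the list alone (camera adjusted p = 3.02e-09). EdgeR called 1291 genes, 72.8% of them higher (55.9% of 1502 without clusters 10 and 14), 315 without mouse 2 and 522 without mouse 3.

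In cluster 7 the lipopolysaccharide co-receptor gene Cd14 was lower, at 439 ± 128 CPM (-3.01 ± 0.18; SD, n = 3), the NF-κB inhibitor gene Nfkbia at 125 ± 10.8 CPM (-3.29 ± 0.25), Cxcl1 at a fold change of -4.91 ± 0.46 and the phosphodiesterase gene Pde4b at 14.8 ± 2.81 CPM (-3.32 ± 0.15). Areg was lower (-5.66 ± 0.95, on 10 UMIs). Tnfaip8l2 (2.02 ± 0.10), the MHC class II ubiquitin ligase gene March1 (1.86 ± 0.11), the transcription factor genes Maf (1.26 ± 0.14) and Cebpd (1.36 ± 0.15), Sesn1 (2.09 ± 0.15), Arl11 (1.88 ± 0.12) and Tifab (1.71 ± 0.11) were higher. Chemokine genes were lower for 11 of 21 and higher for 0, 12 lower adjusted over the list alone (camera adjusted p = 1.69e-10). Growth and angiogenic factor genes were lower for 11 of 22 and higher for 3, 12 and 5 adjusted over the list alone (camera adjusted p = 5.79e-05), and dissociation and heat stress genes lower for 16 of 26 and higher for 4, 17 and 4 adjusted over the list alone (camera adjusted p = 1.88e-11). EdgeR called 2644 genes, 65.1% of them higher (53.5% of 3073 without clusters 10 and 14), 1149 without mouse 2 and 1567 without mouse 3.

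Outside the lists, the cycling-like cells, named from genes of the cell cycle, were higher for the kinetochore gene Spc24 (3.59 ± 0.11; 68.6 ± 10.9 CPM, SD, n = 3), Tacc3 (3.22 ± 0.11) and the ribonucleotide reductase gene Rrm1 (2.56 ± 0.10). The interferon-induced chemokine gene Cxcl10 (1.87 ± 0.27) and the sterol synthesis gene Idi1 (0.95 ± 0.17) were higher. Apoe, which encodes apolipoprotein E (-1.03 ± 0.19), the phospholipase gene Pla2g7 (-1.03 ± 0.11) and the Fc receptor gene Fcgr4 (-1.02 ± 0.15) were lower. Oxidative phosphorylation genes were higher for 19 of 30, 22 adjusted over the list alone (camera adjusted p = 4.73e-04, and adjusted p = 0.393 with an estimated correlation), a call that ended without clusters 10 and 14, where 11 were higher (camera adjusted p = 0.105). Lipid handling genes were lower for 16 of 31 and higher for 2, 20 and 2 adjusted over the list alone (camera adjusted p = 6.70e-06), and immune checkpoint and regulation genes lower for 11 of 25 and higher for 1, 12 and 1 adjusted over the list alone (camera adjusted p = 3.84e-04). EdgeR called 2395 genes, 65.6% of them higher (52.7% of 2914 without clusters 10 and 14), 1075 without mouse 2 and 1162 without mouse 3.

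In the interferon-like class the chemokine genes Cxcl9 (4.37 ± 0.58; 130.2 ± 172 CPM, SD, n = 3) and Cxcl10 (3.41 ± 0.33), whose products attract T cells, were higher. So were the complement gene Cfb (2.82 ± 0.23), Nlrc5, the transactivator of MHC class I genes (1.99 ± 0.26), the RNA sensor gene Ddx58 (3.27 ± 0.17), Herc6 (3.17 ± 0.13) and the GTPase gene Irgm1 (2.86 ± 0.16). MHC class I and peptide loading genes were higher for 17 of 22 and lower for 0, 19 higher adjusted over the list alone (camera adjusted p = 2.62e-51). Immune checkpoint and regulation genes were higher for 8 of 25 and lower for 0, 8 and 1 adjusted over the list alone (camera adjusted p = 2.25e-06). EdgeR called 441 genes, 392 higher and 49 lower (342 and 84 without clusters 10 and 14), 715 without mouse 1, 210 without mouse 2 and 130 without mouse 3.

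Cluster 9, led by Retnla, Lyz1 and Ifitm6, was higher for the fibronectin gene Fn1 (3.46 ± 0.27; 2533 ± 374 CPM, SD, n = 3), the metalloproteinase gene Mmp19 (3.20 ± 0.19), Timp1 (3.75 ± 0.24) and the serpin gene Serpinb2 (6.19 ± 0.41; 18.5 ± 14.2 CPM). Serpinb2 was at 30.6 and 22.2 CPM in mice 2 and 3. In mouse 1, with 13 cells, it was at 2.71 CPM, below the 5.05 CPM of cluster 10. Irf4 (3.47 ± 0.17), Ccl6 (3.19 ± 0.21), Ccl24 (4.02 ± 0.34) and Areg (2.78 ± 0.31) were higher, as were the coagulation factor VII gene F7 (4.53 ± 0.22), Hopx (3.19 ± 0.17) and Mcub (3.18 ± 0.11), a regulator of mitochondrial calcium uptake. Apoe (-1.09 ± 0.18) and Acp5 (-0.93 ± 0.21), genes of a lipid carrier and a lysosomal enzyme, were lower, as were Ms4a7 (-0.87 ± 0.14), Cd82 (-0.85 ± 0.13) and Hpgds (-0.80 ± 0.12). Chemokine genes were 10 higher and 2 lower of 21, the same adjusted over the list alone (camera adjusted p = 1.87e-06, and adjusted p = 0.0510 with an estimated correlation). Matrix and protease genes were 9 higher and 5 lower of 30, 10 and 6 adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.260 with an estimated correlation). Camera put that list higher and its mean log2 fold change was 0.65, while its median was -0.07. Cells of this cluster had a median of 29350 UMIs. EdgeR called 1673 genes, 1177 higher and 496 lower (1135 and 724 without clusters 10 and 14), 483 without mouse 2 and 766 without mouse 3.

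Over the 10 classes fitted together, camera with a preset correlation called 77 of 140 pairs of list and class, 29 of which held with an estimated correlation. Lists that were called at both settings included glycolysis and oxidative phosphorylation in the hypoxia-like class, chemokines in clusters 2, 3 and 7 and in the lipid-associated-like class, and dissociation and heat stress in clusters 3, 5, 7 and 10. The chemokine and complement lists of the LYVE-1 resident-like class (adjusted p = 0.0277 and 0.0401 with an estimated correlation, camera) and the MHC class I list of the interferon-like class (adjusted p = 7.30e-04, camera) held as well. The median, mean and test also differed in sign for transcription factors in cluster 14 (camera higher, median -0.28, mean -0.09) and complement in the lipid-associated-like class (camera lower, median 0.03, mean -0.22). Neither of these held with an estimated correlation (camera, adjusted p = 0.384 and 0.309 with an estimated correlation). The median fold change of all genes tested was -0.36 in cluster 14 and 0.12 in cluster 7, and nearer to 0 in the other classes.

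**Figure D3:**
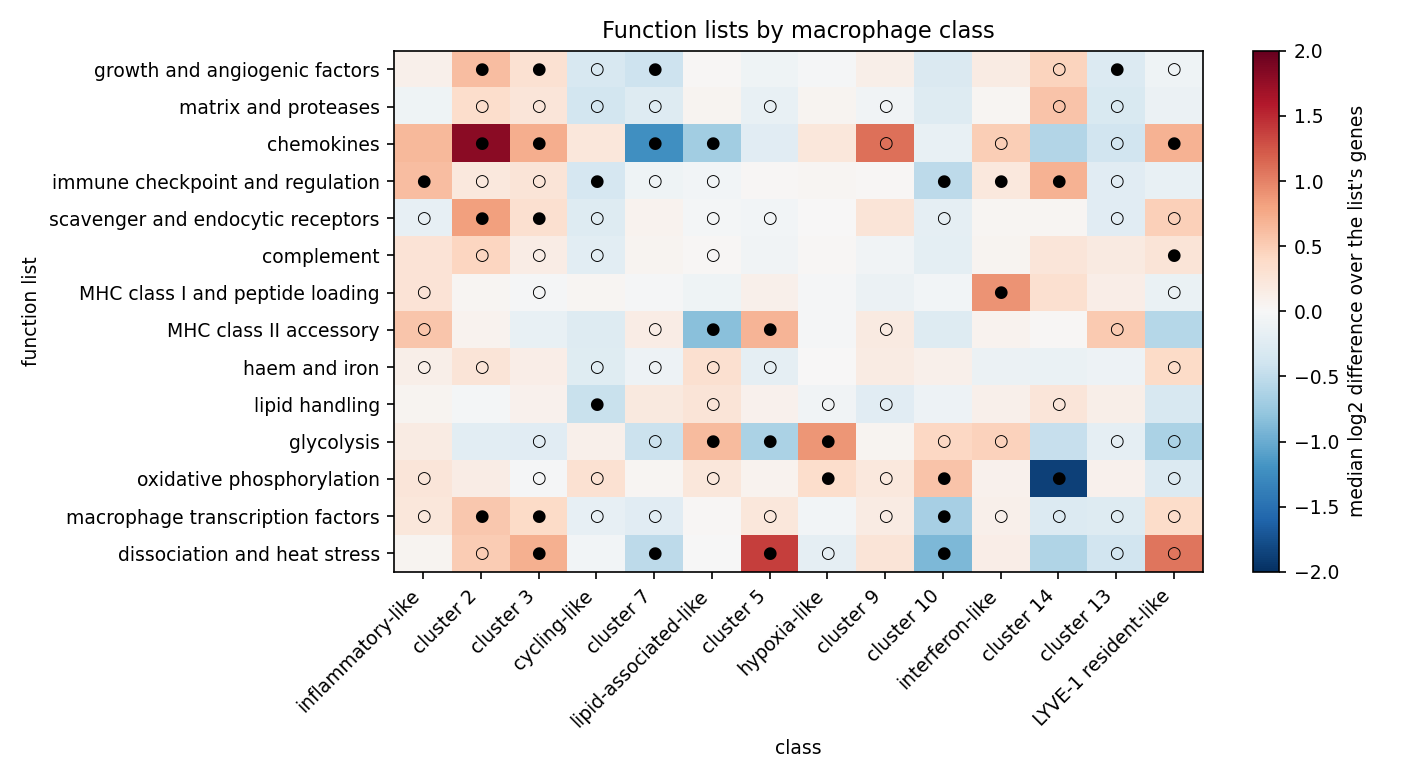
Median log2 difference of each function list (vertical axis) in each macrophage class (horizontal axis), as colour from blue below 0 to red above 0, on a scale that ends at 2 in either direction. Open circles mark lists called by camera at the preset correlation and filled circles those also called with an estimated one; medians run from -1.87 (oxidative phosphorylation, cluster 14) to 1.81 (chemokines, cluster 2).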

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

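The tests of cluster 9 as doublets were fixed before their result was seen, and the tests of clusters 3, 5 and 14 only after. Among the barcodes removed by the filters, which no comparison uses, UMIs of the macrophage gene Adgre1 were found in 56.2% of mouse 1, 28.5% of mouse 2 and 26.8% of mouse 3. An Adgre1 UMI was found in 16.7% of tumour epithelium-like cells. The Adgre1 level was 434, 277 and 284 CPM in the removed barcodes of mice 1, 2 and 3 and 54.2 CPM in the tumour epithelium-like cells, with median UMI counts of 2925, 1662.5 and 1077 and 3353.5. The median mitochondrial shares of the removed barcodes were 29.5, 22.4 and 18.95%. The cells kept also held 54 tumour epithelium-like cells and 11 T cell-like cells, which stayed out of the comparisons.

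Heat-shock and immediate-early genes were higher in cluster 5. Among the cells kept, the median mitochondrial share of cluster 5 was at most 1.04 times the median of the other macrophage classes. Its UMIs were 1.02, 0.799 and 0.813 times the median of mice 1, 2 and 3. The filters had already removed the barcodes with the highest mitochondrial shares, so these values cannot decide on damaged cells, which stay open. A response to dissociation or sorting may account for the 23 higher members of the list, and stays open because no undissociated cells were analysed here. It stays open for other classes too. At the preset correlation camera also put the list higher in cluster 3 (20 of 26 genes higher), cluster 2 (13 of 26) and the LYVE-1 resident-like class. No biological explanation was tested, since the design has 1 group.

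Clusters 3 and 9 had the highest median UMI counts over all cells, and per mouse 1.48, 2.07 and 2.06 and 1.87, 2.77 and 2.49 times the median of mice 1, 2 and 3. A doublet of average cells of other clusters lies between their levels, so such doublets alone are argued against for cluster 9. There, 33 of 495 higher genes at 50 CPM or more (6.67%) lay above each other cluster in all 3 mice. Fn1 was at 2796, 2516 and 2179 CPM in cluster 9 and at 1200.3, 385 and 655 CPM in the next class, though the share passed the preset bound of 5% by a narrow margin. The test used cluster means, so doublets of cells above their cluster's mean, or of cell types without a cluster, stay open. Cluster 9 had a median doublet score of 0.0968, and 13 cells in mouse 1. For cluster 3 the share was 0.337% (1 gene of 297), so doublets may contribute and cannot be told apart from cells with more RNA. No biological explanation was tested.

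Cells of cluster 14 had few UMIs and a nuclear transcript, Malat1, in excess. Few UMIs alone are argued against, since the Malat1 share was at least 11.4 times that of cluster 10, which has as few. Cluster 10 also had the lowest Malat1 share of the macrophage classes (0.151, 0.520 and 0.871%), which raises that ratio. Loss of cytoplasmic RNA may account for it, since the Malat1 share was at least 3.87 times the median of the other macrophage classes, and highest, with ribosomal protein genes lowest, in 3 of 3 mice. No biological explanation was tested.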

How the results depend on the processing

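Among the alternative settings, the tests chosen after the results were seen were the 3-cell minimum, the fits without clusters 10 and 14, the removal of doublets at the expected rate and the limit of 25% mitochondrial UMIs, and the other settings given in this part were fixed before the data were examined. Over 4720 pairs of a named gene and a setting, 4110 had the same direction and side of the threshold, 580 had the same direction short of the threshold and 30 had the other direction. Where a class or gene was absent from a setting there was no pair, so results that could not be compared are not counted. For function lists 954 of 1135 pairs were as reported, 180 fell short of the threshold and 1 had the other direction. Class shares moved by less than the SD between mice in 126 of their alternatives and by more in 46, and numbers of genes called were within 1.5 times the reported number in 170 and outside it in 82. The 126 include the shares without each mouse in turn, whose mean cannot move by as much as the SD of 3 mice. Clusterings without a counterpart of a class gave no share, and are in neither count. Of 10 alternative clusterings, a counterpart was found in 10 for the LYVE-1 resident-like class, the inflammatory-like, interferon-like and cycling-like classes and clusters 7, 9 and 10, in 9 for cluster 5, 7 for the hypoxia-like class, 6 for clusters 13 and 14, 5 for clusters 2 and 3 and 4 for the lipid-associated-like class. For a named class, a counterpart was any class that took the same name, whatever its cells. Where the LYVE-1 resident-like class grew it took in cells of other classes, and 86.2 to 99.03% of its cells stayed in it over these clusterings. Those cells made up 97% of the class so named with genes scaled over all cells and 97.1% with doublets removed at the expected rate. In the other clusterings they made up only 3.70 to 29.5% of it. Of simulated log2 changes of 1, 92.2% were called in the inflammatory-like class, 36.4% in the LYVE-1 resident-like class and 29.7% in cluster 14. Fits on equal cell numbers, on separate UMIs or without a mouse rest on fewer counts or libraries, and for the other moves listed here the cause was not tested.

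At Leiden resolution 0.5, class shares were 23.99% (LYVE-1 resident-like), 11.2% (cluster 5), 14.1% (cluster 7), 7.42% (cycling-like), 16.7% (hypoxia-like) and 16.5% (inflammatory-like). Gene numbers at Leiden resolution 0.5 were 3043 (LYVE-1 resident-like) and 2745 (cluster 9). Several log2 fold changes at Leiden resolution 0.5 had the other sign, at 0.0519 (Vat1 in cluster 5) and 0.57 (Vegfa in LYVE-1 resident-like class). At Leiden resolution 1.5, class shares were 2.95% (LYVE-1 resident-like), 8.84% (cluster 2), 7.28% (cluster 3), 3.11% (hypoxia-like) and 19.1% (inflammatory-like). Gene numbers at Leiden resolution 1.5 were 271 (cluster 3) and 1904 (hypoxia-like). Several log2 fold changes at Leiden resolution 1.5 had the other sign, at 0.0818 (Havcr2 in cluster 3), -1.54 (Areg in hypoxia-like), -0.39 (Cxcl3 in hypoxia-like), -1.41 (Thbs1 in hypoxia-like), -0.78 (Il1rn in hypoxia-like), 0.0248 (Hspa1a in hypoxia-like), 0.38 (Abi3 in hypoxia-like), 0.0455 (Ccl8 in inflammatory-like) and 0.30 (Mmp2 in LYVE-1 resident-like class). With 4000 variable genes, class shares were 27.5% (LYVE-1 resident-like), 13.5% (cluster 7), 6.85% (cycling-like) and 13.9% (inflammatory-like). Gene numbers with 4000 variable genes were 617 (cluster 5), 600 (LYVE-1 resident-like) and 236 (interferon-like). A log2 fold change with 4000 variable genes had the other sign, at 0.42 (Vegfa in LYVE-1 resident-like class). With genes scaled over all cells, class shares were 13.9% (cluster 7) and 20.5% (inflammatory-like). Gene numbers with genes scaled over all cells were 877 (cluster 10), 149 (cluster 3), 394 (cluster 5), 396 (lipid-associated-like) and 281 (interferon-like). With at least 1000 genes per cell, class shares were 18.2% (LYVE-1 resident-like), 1.45% (cluster 10), 1.73% (hypoxia-like), 20.04% (inflammatory-like) and 0.378% (tumour epithelium-like). The number of genes called with at least 1000 genes per cell was 693 (cluster 5). Several log2 fold changes with at least 1000 genes per cell had the other sign, at 0.43 (Mmp2 in LYVE-1 resident-like class), 0.14 (Mmp14 in LYVE-1 resident-like class) and 0.73 (Vegfa in LYVE-1 resident-like class). With at most 8% mitochondrial UMIs, class shares were 10.4% (LYVE-1 resident-like), 2.76% (cluster 10), 10.7% (cluster 5), 12.3% (cluster 7), 12.1% (cycling-like), 2.86% (hypoxia-like) and 22.4% (inflammatory-like). Gene numbers with at most 8% mitochondrial UMIs were 945 (cluster 10), 360 (cluster 3), 457 (cluster 5) and 1273 (inflammatory-like). Some log2 fold changes with at most 8% mitochondrial UMIs had the other sign, at 0.31 (Havcr2 in cluster 3), 0.00521 (Pdlim7 in cluster 3), 0.70 (Vegfa in LYVE-1 resident-like class), -0.47 (March1 in cluster 13) and 0.51 (Il1rn in cluster 13). With doublets kept, class shares were 16.8% (LYVE-1 resident-like), 9.47% (cluster 5) and 24.7% (inflammatory-like). The number of genes called with doublets kept was 632 (cluster 5). Several log2 fold changes with doublets kept had the other sign, at 0.38 (F13a1 in inflammatory-like), 0.20 (Ccl8 in inflammatory-like), 0.0794 (Mmp2 in LYVE-1 resident-like class) and 0.51 (Vegfa in LYVE-1 resident-like class). With doublets removed at the expected rate, class shares were 15.3% (cluster 7), 8.03% (hypoxia-like) and 16.1% (inflammatory-like). A log2 fold change with doublets removed at the expected rate had the other sign, at 0.12 (Hspa1a in hypoxia-like). With at most 25% mitochondrial UMIs, class shares were 19.5% (LYVE-1 resident-like), 6.16% (cluster 14), 9.11% (cluster 5), 7.35% (cycling-like) and 20.9% (inflammatory-like). Gene numbers with at most 25% mitochondrial UMIs were 3652 (cluster 14) and 767 (cluster 5). Some log2 fold changes with at most 25% mitochondrial UMIs had the other sign, at 0.0809 (Mmp2 in LYVE-1 resident-like class) and 0.43 (Vegfa in LYVE-1 resident-like class). With clusters and tests on separate UMIs, class shares were 3.91% (LYVE-1 resident-like), 6.22% (cluster 10), 6.04% (cluster 5), 14.1% (cluster 7), 6.88% (cycling-like) and 21.6% (inflammatory-like). Gene numbers with clusters and tests on separate UMIs were 740 (cluster 10), 1251 (cluster 14), 1031 (cluster 2), 341 (cluster 3) and 495 (cluster 5). Some log2 fold changes with clusters and tests on separate UMIs had the other sign, at 0.0374 (Cd52 in cluster 3) and 0.13 (Havcr2 in cluster 3). Marker shares over all barcodes were 86.8% (Ptprc), 60.5% (Itgam) and 78.4% (Adgre1). Marker shares after thinning were 55.2% (Ptprc), 24.4% (Itgam) and 44.1% (Adgre1). Gene numbers without the mouse block were 1432 (cluster 2), 133 (cluster 3), 422 (cluster 5), 1504 (cluster 7), 1039 (cycling-like), 134 (hypoxia-like), 700 (inflammatory-like), 28 (lipid-associated-like), 119 (cluster 13), 660 (cluster 9) and 191 (interferon-like). Gene numbers with equal cell numbers per class were 934 (cluster 10), 985 (cluster 2), 249 (cluster 3), 370 (cluster 5), 996 (cluster 7), 907 (cycling-like), 230 (hypoxia-like), 552 (inflammatory-like) and 82 (lipid-associated-like). Gene numbers against the summed counts of all other cells were 684 (cluster 10), 1405 (cluster 14), 2030 (cluster 3), 1101 (lipid-associated-like) and 937 (LYVE-1 resident-like). A log2 fold change against the summed counts of all other cells had the other sign, at -0.33 (Ccl24 in cluster 3). The chemokine list of the interferon-like class lay lower against the summed counts of all other cells (camera adjusted p = 0.385), and higher in the fit reported (camera adjusted p = 5.60e-04, and adjusted p = 0.146 with an estimated correlation). The number of genes called with the 3-cell minimum was 396 (cluster 3). The number of genes called without the filter on low counts was 448 (cluster 13). The number of genes called by the DESeq2 Wald test was 420 (cluster 13). The number of genes called without clusters 10 and 14 was 1698 (cluster 3). Camera called 29 pairs of list and class with an estimated correlation, against 77 with the preset one. Numbers of genes called without each mouse in turn ran from 865 to 1078 (cluster 10), 1487 to 1913 (cluster 14), 1426 to 2372 (cluster 2), 96 to 763 (cluster 3), 315 to 1417 (cluster 5), 1149 to 2839 (cluster 7) and 1075 to 2662 (cycling-like). For the other classes that moved they ran from 154 to 1124 (hypoxia-like), 607 to 1797 (inflammatory-like), 57 to 929 (lipid-associated-like), 565 to 1782 (LYVE-1 resident-like), 50 to 440 (cluster 13), 483 to 1990 (cluster 9) and 130 to 715 (interferon-like).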

Other observations

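The tests with class labels permuted within mice were chosen after the results were seen. Cluster 10, with median UMIs of 2869, 2336.5 and 1929.5 in mice 1, 2 and 3, had the lowest Malat1 share of UMIs (0.151, 0.520 and 0.871%) and the highest share of ribosomal protein genes (20.8, 15.8 and 14.9%) of the macrophage classes in each mouse. Dissociation and heat stress genes were lower for 19 of 26, 21 adjusted over the list alone (camera adjusted p = 5.38e-19), and transcription factor genes for 16 of 36, the same adjusted over the list alone (camera adjusted p = 9.61e-11). Oxidative phosphorylation genes were higher for 21 of 30, 24 adjusted over the list alone (camera adjusted p = 2.47e-22), such as Uqcrq (0.84 ± 0.11; 436 ± 23.2 CPM, SD, n = 3). Ccl8 (2.27 ± 0.41), Gapdh (0.95 ± 0.13) and Tnfaip8l2 (1.18 ± 0.18) were higher. The mRNA processing gene Pnisr (-1.72 ± 0.26) and Zfp638 (-1.69 ± 0.28) were lower. EdgeR called 1566 genes, 902 higher and 664 lower, and 865 without mouse 2.

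Cluster 14 had Malat1 at 17.4, 8.21 and 9.92% of UMIs, ribosomal protein genes at 3.13, 3.47 and 5.02%, median mitochondrial shares of 6.99, 10.2 and 9.65% in mice 1, 2 and 3, and a median log2 fold change of -0.36 over all genes tested. Genes of oxidative phosphorylation were lower for 29 of 30, the same adjusted over the list alone (camera adjusted p = 3.58e-31), among them the cytochrome c gene Cycs (-2.53 ± 0.29, on 12 UMIs). The NF-κB subunit gene Nfkb1 (2.22 ± 0.15; 1308 ± 346 CPM, SD, n = 3), the cystine transporter gene Slc7a11 (2.79 ± 0.28) and Ciita (1.94 ± 0.32) were higher. Immune checkpoint and regulation genes were 10 higher and 3 lower of 25, 11 and 3 adjusted over the list alone (camera adjusted p = 8.81e-06). Matrix and protease genes were 8 higher and 1 lower of 28, 9 and 1 adjusted over the list alone (camera adjusted p = 5.56e-05, and adjusted p = 0.0800 with an estimated correlation). EdgeR called 2278 genes, 608 higher and 1670 lower, and 1487 without mouse 2. Cluster 13 was higher for the immediate-early gene Egr1 (1.92 ± 0.27; 272 ± 26.9 CPM, SD, n = 3), Atf3 (1.28 ± 0.14) and the kinase gene Rps6kb1 (2.78 ± 0.27), and lower for Vegfa (-2.30 ± 0.37). Growth and angiogenic factor genes in cluster 13 were lower for 2 of 22, the same adjusted over the list alone (camera adjusted p = 1.76e-05). Dissociation and heat stress genes there were 4 higher and 4 lower of 26, 4 and 9 adjusted over the list alone (camera adjusted p = 0.0248, and adjusted p = 0.491 with an estimated correlation), and camera put the list lower. That call was lost without mouse 3 (camera adjusted p = 0.0739). In cluster 13 edgeR called 279 genes, 176 higher and 103 lower (205 and 130 without clusters 10 and 14), 440 without mouse 1, 118 without mouse 2 and 50 without mouse 3.

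Permuting class labels within mice gave 60 splits for each of the 10 classes fitted together, the real one included. The classes were formed from the expression of the same cells, so real labels call more genes than permuted ones by construction, and these counts say nothing on chance. As many genes as reported were called by the real split alone (1 of 60). The highest other split called 392 genes against 666 in the lipid-associated-like class, 202 genes against 827 in cluster 3 and 227 genes against 2395 in the cycling-like class. In clusters 2, 5, 7, 10 and 14 it called 3, 174, 48, 305 and 305 against 2519, 1291, 2644, 1566 and 2278, and in the inflammatory-like and hypoxia-like classes 114 and 1 against 1919 and 1127. The same limit holds for the 4 classes of the 3-cell fit, with 1 of 40 splits. The highest other called 202 against 1596 in the LYVE-1 resident-like class, 100 against 441 in the interferon-like class, and 128 and 120 against 1673 and 279 in clusters 9 and 13.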
